A study of Mus musculus with 23 samples.

How the data were processed

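Transcript levels were measured in pools of whole mouse embryos with CodeLink 1-colour arrays, in which biotin-labelled cRNA is detected with Alexa-647 streptavidin, per the labels' protocols. Embryos of day 8.5 came from matings of p53 heterozygous mice and spent 10 minutes in a water bath at 38 °C (control) or 43 °C (heat), per the labels. Each pool held 3 to 7 embryos of the same genotype and bath. The 23 arrays fall into 6 groups by genotype (wildtype, heterozygous or null for p53) and bath, with 4 pools in each group except null heat, which has 3 here. A 4th null heat pool was not analysed here. The time from bath to collection, the scanner, the background step, the normalization and the spot filter are not given in the sources used here.

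The deposited values are linear intensities, and each array has a median over all 36227 probes near 1 when empty cells are counted as low. The authors' columns differ by bath. The 12 control columns hold 7576 to 11666 empty cells each and no value at or below 0. The 11 heat columns hold no empty cell, 129 to 203 cells with a code for missing and 68 to 152 other values at or below 0. The empty control cells are not random: 95.2% of the cells of probes with a median under 0.25 on the heat arrays are empty, against 1% at medians from 2 to 100 and 98.1% above 256. Thus the dimmest and the brightest transcripts were left out, among them 56 probes that are empty in at least 10 of the 12 controls and above 3 on at least 8 heat arrays. As a probe needed values in every group, this holds for all 12 comparisons, those between heat pools included. The highest value on an array ran from 181.5 (heterozygous control B) to 488.3 (null heat C). No scan date, slide or batch was available in these tables, so bath and any difference in array processing cannot be told apart.

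Coded and empty cells were set to missing. Values at or below the 5th percentile of an array's positive values were set to that percentile before log2. The medians of the 18699 probes with a value on all arrays spanned 0.337 on the log2 scale, over the limit of 0.1 fixed before the data were examined, so quantile normalization was used, and each array centred on its median was tried beside it. A probe was tested with at least 3 values in each group and a value above its array's 40th percentile on at least 3 arrays, which left 21979 probes. Gene symbols came from GEO's platform annotation, updated by gene ID through a RefSeq gene table (assembly GRCm38.p6, used only for names and neighbouring genes). Of the probes, 21615 have 1 symbol (21487 matched by ID), 681 several and 13931 none listed; 14500 tested probes name 12651 genes. A gene is represented by its probe of highest mean log2 value. No tested probe carries the symbol Trp53, so the targeted gene was not analysed here and the genotype labels could not be checked with it.

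Differences were fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, in a model of 6 group means over all 23 arrays, which share 1 estimate of the spread per probe. The 12 comparisons are heat against control in each genotype, each pair of genotypes in each bath, and the 3 differences between heat responses. Adjusted p-values are limma's two-sided values after Benjamini-Hochberg adjustment over the probes of a comparison, with 0.05 as threshold. "Rose" and "fell" are used for genes past it. Errors of log2 fold changes are standard errors, and errors of intensities are SDs over pools. The labels call the pools biological replicates; nothing names their litters, so the p-values measure the spread between these pools only. The number of arrays limits the precision.

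Before the data were examined, 24 gene lists were fixed: p53 targets, heat shock, endoplasmic reticulum stress, immediate early, apoptosis, G1/S, G2/M, oxidative and metal stress, hypoxia and glycolysis, cholesterol synthesis, neural tube, neural crest, somite, heart muscle, primitive red cell, endothelium, yolk sac, trophoblast and decidua, gut and epithelium, immune, sex-linked, ribosomal protein and replication-dependent histone genes, and genes within 10 Mb of Trp53. They were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 24 lists. Camera takes no missing values, so 0.716% of the cells were filled with their group mean. Of 40 calls at the preset correlation 5 hold with an estimated one: p53 targets with heat in wildtype pools, in null and in heterozygous against wildtype heat pools and in the difference between the heterozygous and wildtype heat responses, and cholesterol synthesis with heat in heterozygous pools.

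The rule for named genes, also fixed before, allows the 10 largest rises and falls past the threshold whose arrays do not overlap between the groups (for differences of responses the 10 largest), the 4 members of smallest p of a list, or 2 where none passed, and 14 p53 targets, heat shock genes and sex markers given wherever measured. The text names a part of what the rule allows, picked after the values were seen and after it was known which calls other settings end. That choice raises the share of named calls that hold under every setting: 48 of 171 hold, and before genes were dropped from the text the share was lower. Of the 14, Bax, Xist and Ddx3y had no tested probe. Coordinates are not given because the platform annotation names no build.

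The fit was tested on simulated data with 200 of the 21979 probes changed. At a 2-fold change it recovered 96% for heat in wildtype pools, 90% for null against wildtype controls, 82% for null against wildtype heat pools and 74% for the difference of their heat responses. At 1.5-fold it recovered 60%, 48%, 46% and 18%. Unchanged probes made up 3.26%, 1.17%, 5.2% and 4.64% of the calls. The simulated errors were independent between probes and between pools. These shares therefore do not cover a structure that many probes share, such as the splits of pools described below.

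Alternatives planned were the median centring, other floors and filters on dim or incomplete probes, a fit of the compared groups alone, eBayes without trend or robust, array weights, the replicate letter as a block, 1 probe per gene, averaged probes for lists, and each pool left out. After seeing the data 6 were added: values as deposited, 1 floor for all arrays, the array's highest value as a covariate, a score of each array on the split within the heterozygous controls as a covariate, the 4 arrays of lowest highest value left out, and wildtype heat B and null heat B left out, which were chosen for their Hspa1a level.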

Results

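The series asked how transcript levels in mouse embryos depend on p53, a transcription factor that acts after cellular stress, and on a brief bath at a raised temperature. Whole embryos of day 8.5, when the neural tube closes, were bathed for 10 minutes at 38 °C or 43 °C and pooled by genotype. The 6 groups were wildtype, heterozygous and null control pools (n = 4 each), wildtype and heterozygous heat pools (n = 4 each) and null heat pools (n = 3). Intensities are given in the arrays' relative units after quantile normalization. All adjusted p-values are from limma, and log2 fold changes are given ± SE.

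In wildtype embryos Hspb1, a small heat shock protein, rose with heat by 2.39 ± 0.11 (adjusted p = 5.1e-12), from 17 ± 1.3 in the 3 control pools with a value to 89.3 ± 8.06 in the 4 heat pools. Tcte3, a dynein light chain of the testis, rose by 2.94 ± 0.11 (adjusted p = 2.5e-13). Rbmxl2, an RNA-binding protein of male germ cells, rose by 1.94 ± 0.13, and Smc1b, a cohesin subunit of meiosis, by 1.41 ± 0.14. The stress kinase gene Mapkapk3 rose by 1.81 ± 0.17, the keratin gene Krt19 by 0.59 ± 0.10 and the adaptor gene Crk by 0.70 ± 0.13. Of 45 measured p53 targets 13 rose and 0 fell (15 and 0 adjusted over the list alone). Their median change was 0.27 (camera adjusted p = 3.5e-10, and adjusted p = 0.025 with an estimated correlation), and 0.158 without wildtype control D, 0.17 without heat C and 0.139 in values as deposited. The list's score per array was 0.45, 0.64 and 0.35 in wildtype heat A, C and D, where Hspa1a was high, and 0.15 in B, where it was not. Cdkn1a, the cell cycle inhibitor p21, rose by 2.14 ± 0.49, and the apoptosis genes Pmaip1 (Noxa) and Bbc3 (Puma) rose by 2.0 ± 0.26 and 1.03 ± 0.18. Ccng1, cyclin G1, rose by 1.56 ± 0.19, Phlda3 by 1.52 ± 0.18, Sesn2 by 1.14 ± 0.19 and Dcxr by 1.11 ± 0.12. Outside that list 1700007K13Rik rose by 2.68 ± 0.20 (adjusted p = 9e-08).

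Of 18 cholesterol synthesis genes 4 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.411. The list had a camera adjusted p of 3.7e-08 and an adjusted p of 0.052 with an estimated correlation. Those 4 act in the mevalonate pathway: Pmvk at -0.36 ± 0.07, Mvd at -0.68 ± 0.15, Fdps at -0.51 ± 0.12 and Idi1 at -0.80 ± 0.20. Of 32 heat shock genes 5 rose and 0 fell (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.026 and an adjusted p of 0.57 with an estimated correlation. Beside Hspb1 these were Hspb8 (1.01 ± 0.21), Hsp90aa1 (0.39 ± 0.09), and the inducible Hsp70 genes Hspa1a (5.17 ± 1.18, adjusted p = 0.017) and Hspa1b (3.47 ± 0.81). Hspa1a was at 78.8 to 122 on 3 heat arrays and at 0.881 on wildtype heat B. Hsph1 (0.44 ± 0.25, adjusted p = 0.36) and Dnajb1 (-0.07 ± 0.19, adjusted p = 0.86) did not pass. Mt1, a metallothionein, rose by 1.06 ± 0.15, and Sqstm1, an autophagy receptor, by 0.46 ± 0.10. Hsp90aa1 and Sqstm1 missed the threshold when arrays were centred on their medians. The homeobox genes Alx1 and Barx1 fell by 0.59 ± 0.12 and 0.61 ± 0.13, and the largest named falls were Adpgk at -2.69 ± 0.64, Gpc6 at -1.41 ± 0.27 and Pdzph1 at -1.25 ± 0.15. A second Gpc6 probe did not pass (-0.80, adjusted p = 0.11). The DNA repair gene Rad51b fell by 0.89 ± 0.12, Hspb3, a small heat shock protein gene outside the fixed list, by 0.88 ± 0.15 and the histone gene H2ac13 by 0.65 ± 0.12. The apolipoprotein gene Apoa2 of the yolk sac fell by 1.37 ± 0.35, and the yolk sac list had a median of -0.547 with 1 of 28 genes past the threshold (camera adjusted p = 6.9e-06, and adjusted p = 0.62 with an estimated correlation).

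In all 643 probes passed in wildtype pools, 363 higher and 280 lower (56.5% higher). The split was 9.9% higher of 1970 in values as deposited, whose median change over all probes was -0.12 against 0.04 after quantile normalization, and 38.4% of 922 with median centring. With the array's highest value or the split score described below as a covariate the count was 1244 or 1568, and leaving out wildtype control A, C or D gave 403, 365 or 362. Of the 34 named calls, leaving out control A to D ended 4, 1, 5 and 7 and leaving out heat A to D ended 9, 1, 5 and 6; Cdkn1a was lost without control D (adjusted p over the alternatives 0.00014 to 0.061) and without heat A or C, and Hspa1a without control D or heat A, C or D.

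**Figure D1:**
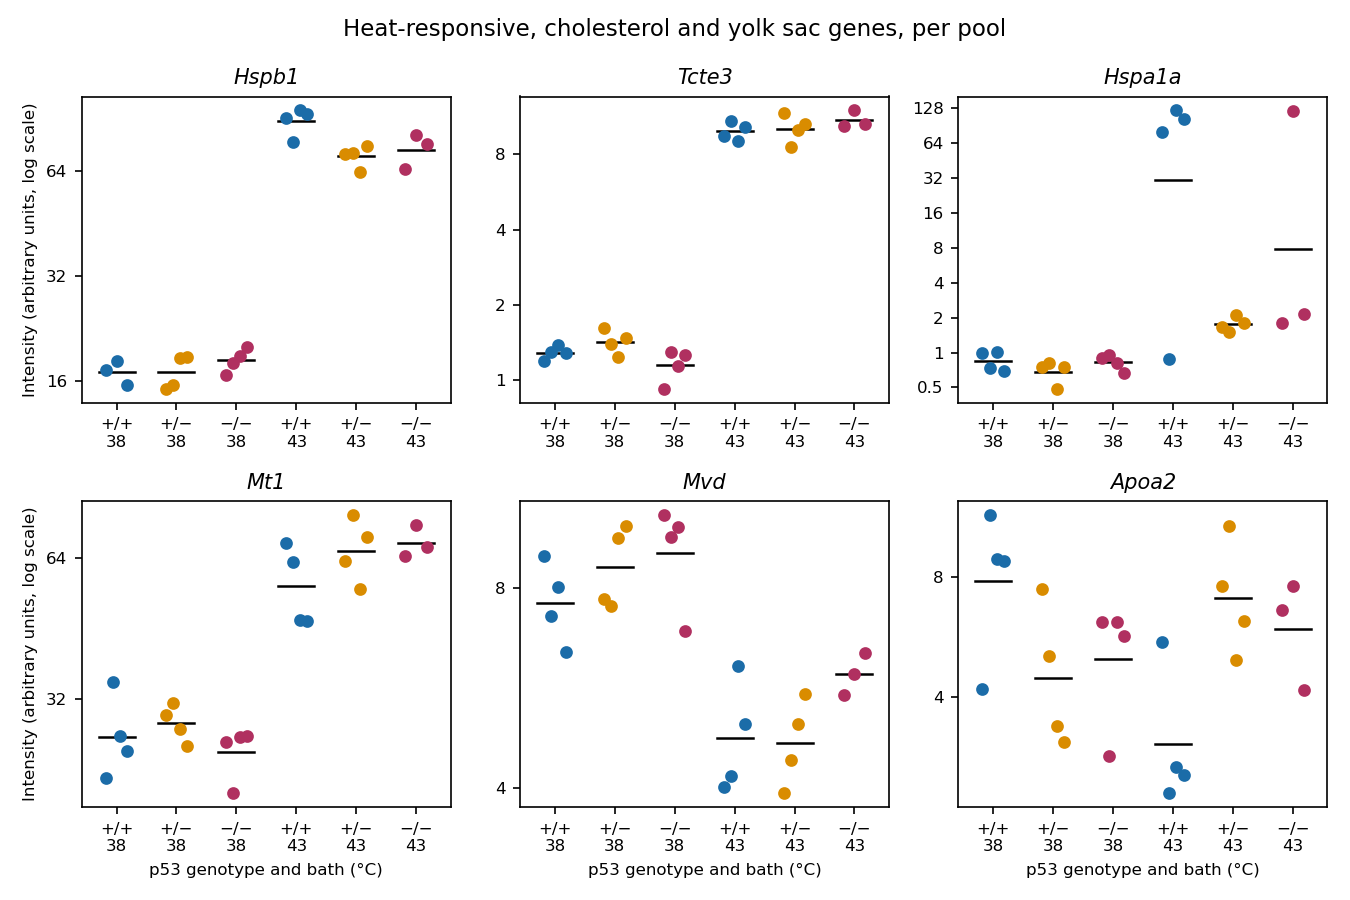
Intensity (arbitrary units, log scale) of 6 genes by p53 genotype and bath temperature in °C. Each point is a pool and each black line a group's geometric mean. All 11 heat pools lie above every control pool with a value for Hspb1 (63.6 against at most 20). The same holds for Tcte3 (8.57 against at most 1.62), while Hspa1a is at 78.8 or more on 4 heat pools. Wildtype control B has no Hspb1 value.

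Heat in heterozygous embryos raised several of these genes. Tcte3 rose by 2.83 ± 0.11 (adjusted p = 5.3e-13), Hspb1 by 2.06 ± 0.10, Rbmxl2 by 1.95 ± 0.14, Smc1b by 1.09 ± 0.14 and the meiotic recombinase gene Dmc1 by 1.03 ± 0.12. Mt1 rose by 1.22 ± 0.15, Crk by 0.83 ± 0.13, Krt19 by 0.65 ± 0.10, Sqstm1 by 0.50 ± 0.10 and Hsp90aa1 by 0.44 ± 0.09. Of the 45 p53 targets 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.22). Ccng1 rose by 1.41 ± 0.19 (adjusted p = 0.00041), from 2.68 ± 0.341 to 7.07 ± 0.586 (n = 4 each), and 1700007K13Rik by 1.12 ± 0.22. Cdkn1a (0.62 ± 0.49, adjusted p = 0.55) and Pmaip1 (0.56 ± 0.26, adjusted p = 0.27) did not pass. Of 18 cholesterol synthesis genes 5 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.461, a camera adjusted p of 4.4e-10 and an adjusted p of 0.04 with an estimated correlation. Fdps fell by 0.79 ± 0.12, Mvd by 0.88 ± 0.15, Pmvk by 0.50 ± 0.07 and Cyp51 by 0.71 ± 0.15 (its other probe -0.64, adjusted p = 0.055). The proneural genes Neurog2 and Neurog1 fell by 0.99 ± 0.19 and 0.80 ± 0.19, Barx1 by 1.08 ± 0.13, Pou3f3 by 1.21 ± 0.26, Gpc6 by 1.47 ± 0.27 (other probe -0.96, adjusted p = 0.092) and the natriuretic peptide gene Nppb by 1.22 ± 0.29. Aqp8, a water channel on the primitive red cell list, rose by 1.24 ± 0.27. Hspa1a did not pass (1.36 ± 1.18, adjusted p = 0.60; heat pools 1.77 ± 0.258, n = 4). The yolk sac list had a median of 0.541 with 0 of 28 genes past the threshold (camera adjusted p = 4.2e-08, and adjusted p = 0.34 with an estimated correlation).

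In heterozygous pools 484 probes passed, 209 higher and 275 lower (43.2% higher, and 20.1% of 398 in values as deposited). With only the heterozygous arrays fitted the count was 56 and 10 of the 23 named calls were lost, and another split of these 8 arrays into 4 and 4 gave 1126. With the array's highest value or the split score as a covariate the count was 1156 or 1262. Without control A, C or D it was 276, 292 or 299, without heat A, B or C 198, 248 or 258, and leaving out control A, C and D ended 1, 3 and 4 named calls and heat A, B and C 4, 4 and 2.

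Heat in null embryos raised Tcte3 by 3.26 ± 0.12 (adjusted p = 1.4e-13), Rbmxl2 by 2.07 ± 0.14, Hspb1 by 2.01 ± 0.11 and Crk by 1.30 ± 0.14. The metallothionein genes Mt1 and Mt2 rose by 1.48 ± 0.16 and 1.03 ± 0.20, and Sqstm1 by 0.61 ± 0.11. With them 3 of 22 oxidative and metal stress genes rose and 0 fell (6 and 0 adjusted over the list alone), with a camera adjusted p of 0.00035 and an adjusted p of 0.071 with an estimated correlation. Of 45 p53 targets 1 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.40). Ccng1 (0.31 ± 0.21, adjusted p = 0.35) and Cdkn1a (1.17 ± 0.53, adjusted p = 0.17) did not pass. Of 32 heat shock genes 4 rose and 0 fell (5 and 0 adjusted over the list alone): Hspb1, Hsp90aa1 at 0.46 ± 0.10, Dnajb6 at 0.66 ± 0.17 (other probe 0.59, adjusted p = 0.041) and Cirbp, a cold-inducible RNA-binding protein, at 0.60 ± 0.15. That list had a camera adjusted p of 0.00076 and an adjusted p of 0.21 with an estimated correlation. Of 26 apoptosis genes 4 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.085), among them Hrk (1.15 ± 0.19), Bok (0.64 ± 0.14) and Bak1 (0.52 ± 0.14), which promote cell death. Of the 4, Bak1 (-0.47, adjusted p = 0.029) and Bcl2l11 (-0.36, adjusted p = 0.043) were lower in null than in wildtype controls. That comparison shares the null control arrays, and Hrk and Bok did not pass in it. Of 34 G2/M genes 3 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 5.3e-05, and adjusted p = 0.21 with an estimated correlation). These were Aurka (0.76 ± 0.20), Bub3 (0.43 ± 0.10) and Cdc20 (0.45 ± 0.12), whose other probes, for Aurka (0.04, adjusted p = 0.88) and Bub3 (-0.06, adjusted p = 0.76), did not pass. Of 18 cholesterol synthesis genes 4 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.051), among them Idi1 at -0.86 ± 0.21, Mvd at -0.60 ± 0.16 and Pmvk at -0.28 ± 0.08.

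Further rises in null pools were Klf3 (1.78 ± 0.33), Resf1 (1.69 ± 0.31; other probe 0.63, adjusted p = 0.17), the erythropoietin receptor gene Epor (1.08 ± 0.22), Dcn (0.97 ± 0.23), Bnip3 (0.74 ± 0.15), Krt19 (0.73 ± 0.11), Cyp26a1 (0.54 ± 0.13), Asns (0.52 ± 0.12), and Bmp2 (0.52 ± 0.11) and Vldlr (0.76 ± 0.19), whose other probes were at 0.02 (adjusted p = 0.95) and 0.06 (adjusted p = 0.83). Plxna1, Ttc9c and Ezh1 fell by 1.71 ± 0.35, 1.71 ± 0.28 and 1.68 ± 0.36, and Wnt3a by 0.48 ± 0.11. Usp9y, a Y-linked gene, rose by 0.54 ± 0.11 (adjusted p = 0.011, and 0.058 with only the null arrays fitted). Hspa1a did not pass (3.23 ± 1.27, adjusted p = 0.12) and stood at 121 on null heat B against 1.79 and 2.13 on the other pools. In all 1131 probes passed, 682 higher and 449 lower (60.3% higher), 533 with only the null arrays fitted and 4809 with the array's highest value as a covariate. With the split score as a covariate 282 passed and 20 of the 34 named calls were lost, among them Ezh1 and Plxna1 (adjusted p = 0.054 each) and Epor (adjusted p = 0.05). In the comparison of null with wildtype controls, which shares the 4 null control arrays, these genes and Ttc9c differed the opposite way (Ezh1 1.97, Ttc9c 1.79, Plxna1 1.78 and Epor -0.89). Without null heat B the count was 260 and 15 named calls were lost; without null control B, C or D it was 283, 574 or 690, with 13, 7 and 7 lost. Leaving out control A, heat A and heat C ended 4, 8 and 4.

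The heat responses of the genotypes shared calls. Of 21979 probes 47 rose in all 3 genotypes (39 named genes, among them Tcte3, Hspb1, Rbmxl2, Mt1, Crk, Krt19, Sqstm1 and Hsp90aa1) and 40 fell (38 named genes, among them Pmvk and Mvd). Wildtype and heterozygous pools, which share no array, had 76 rises and 106 falls in common, against 3.45 and 3.5 for independent lists, and their log2 fold changes correlated at r = 0.41 across probes. Heterozygous and null pools had 96 rises and 85 falls in common (6.49 and 5.62 for independent lists, r = 0.336). Wildtype and null pools had 71 and 49 (11.3 and 5.72, r = 0.024). With each pool left out r ran from 0.24 to 0.476, 0.095 (without heterozygous control C) to 0.568 and -0.095 to 0.132 for these 3 pairs. With the array's highest value as a covariate the last 2 were 0.729 and 0.376. Probes are not independent replicates. The filtering of control and heat columns is common to all 3 contrasts.

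**Figure D2:**
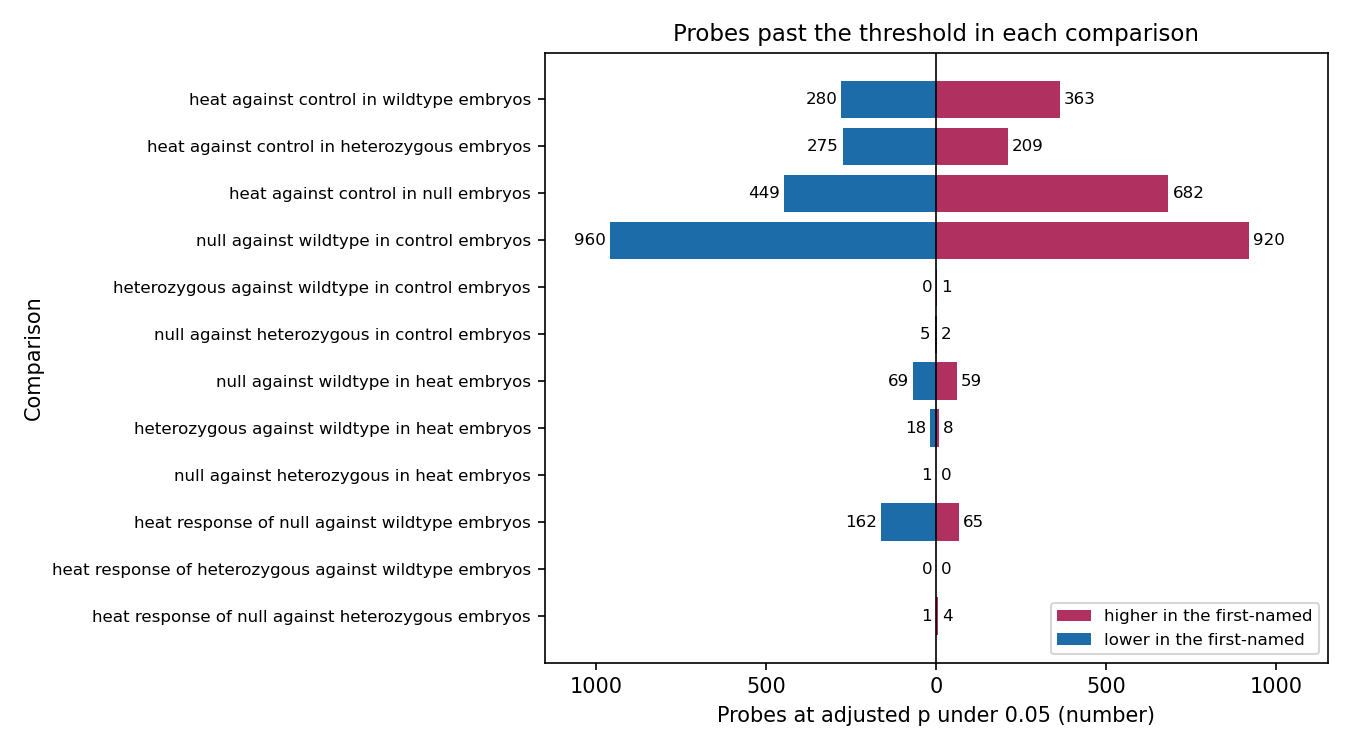
Number of probes at adjusted p under 0.05 in each of the 12 comparisons. Bars to the right count probes higher in the first-named group or response and bars to the left lower ones; 920 and 960 probes differed between null and wildtype control pools, against 59 and 69 between null and wildtype heat pools.

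Null and wildtype embryos were compared first in the control bath, which asks what p53 does without heat. Ccng1 was lower in null pools by -1.47 ± 0.19 (adjusted p = 0.00051), at 1.42 ± 0.143 against 3.93 ± 0.308 (n = 4 each). The difference stayed past the threshold in all 26 alternatives tried (adjusted p at most 0.0044). Of 45 p53 targets 7 were lower and 1 higher (9 and 2 adjusted over the list alone), with a median of -0.131, a camera adjusted p of 0.022 and an adjusted p of 0.60 with an estimated correlation. Cdkn1a was lower by -2.01 ± 0.49, Fbxw7, a ubiquitin ligase subunit, by -1.20 ± 0.28, and the small GTPase gene Rap2b by -0.71 ± 0.13. Other genes lower in null pools were Pkm, pyruvate kinase, at -2.84 ± 0.56, Csk at -2.82 ± 0.58, the replication helicase gene Mcm7 at -2.60 ± 0.60, Krt8 at -2.37 ± 0.59, the splicing factor gene Sf1 at -2.35 ± 0.58 and Prkaca at -2.31 ± 0.49. Ezh1, a histone methyltransferase, was higher by 1.97 ± 0.33, Ttc9c by 1.79 ± 0.26, Plxna1 by 1.78 ± 0.32 and Rock1 by 1.15 ± 0.23.

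Among the tissue lists 3 of 21 primitive red cell genes were lower and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.60 with an estimated correlation), among them the globin regulator Klf1 (-1.08 ± 0.22) and Epor (-0.89 ± 0.21). Of 31 heart muscle genes 3 were lower and 0 higher (4 and 0 adjusted over the list alone, camera adjusted p = 0.022, and adjusted p = 0.60 with an estimated correlation), with Hspb7 at -0.93 ± 0.25. Of all 12651 genes 1093 passed in this comparison, and the heart muscle count lies near that share. Of 25 endothelial genes 3 were lower and 1 higher (camera adjusted p = 0.19), with Cldn5 at -1.31 ± 0.28 and Cd34 at -1.16 ± 0.27. Of 11 histone genes 3 were lower and 0 higher (camera adjusted p = 0.0057, and adjusted p = 0.60 with an estimated correlation), with H2ac8 at -1.33 ± 0.31 and H3c4 at -1.02 ± 0.19. The brain gene Otx2 was at -0.95 ± 0.27 and Rax at 0.60 ± 0.17, and the retinoic acid synthesis gene Aldh1a2 was higher by 0.72 ± 0.18. The mitotic checkpoint gene Bub1b was lower by -1.49 ± 0.37 and the glutathione reductase gene Gsr by -1.24 ± 0.30. The Y-linked gene Usp9y was at -0.50 ± 0.11 (adjusted p = 0.014, and 0.051 without null control D). Yolk sac genes had a median of -0.3 with 0 of 28 past the threshold (camera adjusted p = 0.0057, and adjusted p = 0.83 with an estimated correlation). In all 1880 probes passed, 920 higher and 960 lower (48.9% higher, and 37% of 1303 in values as deposited), 4651 with only these arrays fitted, 6061 with array weights and 1079 with the array's highest value as a covariate.

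These differences run along a split between heterozygous control pools A and B and pools C and D. With each array's score on that split, which separates null from wildtype controls completely, as a covariate 12 probes passed, 25 of the 27 named calls were lost and Ccng1 was at -1.54 ± 0.23 (adjusted p = 0.0044). Leaving out wildtype control A, B, C or D gave 815, 524, 846 or 443 probes with 3, 3, 2 and 6 named calls lost, and leaving out null control B, C or D gave 348, 725 or 490 with 10, 9 and 12 lost.

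**Figure D3:**
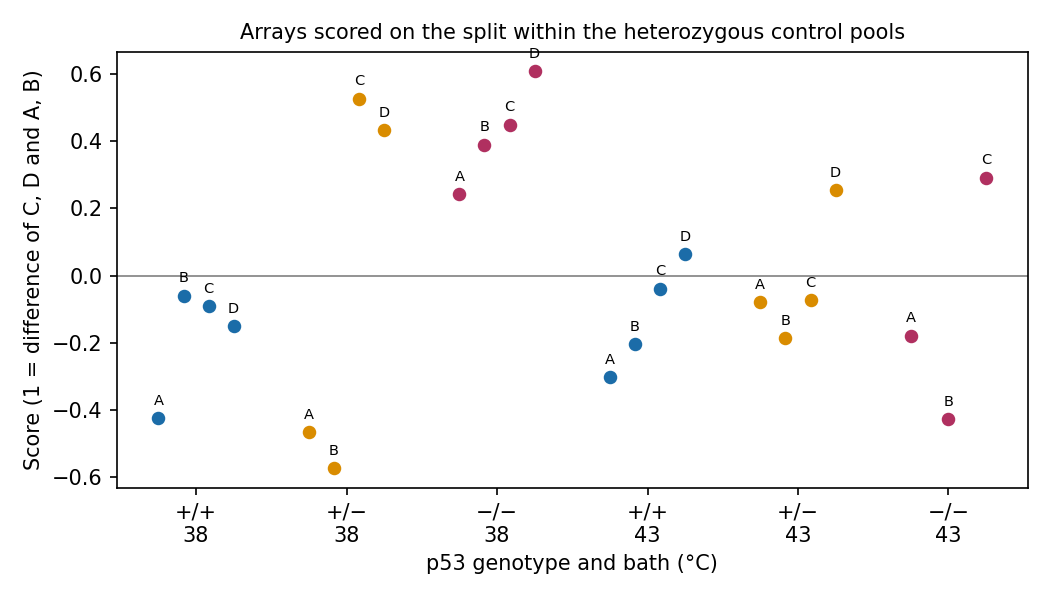
Score of each array on the difference between heterozygous control pools C and D and pools A and B, by p53 genotype and bath temperature in °C. Each point is a pool with its letter; wildtype control pools lie from -0.424 to -0.06 and null control pools from 0.243 to 0.608, on the sides of heterozygous control pools A and B (-0.467 and -0.574) and C and D (0.526 and 0.433).

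Heterozygous and wildtype control pools differed at 1 probe, of Dennd5b, at 1.03 ± 0.12 (adjusted p = 0.00099). Of 21979 probes 1389 had an unadjusted p under 0.05, where no difference would give a share of 0.05. Dennd5b was named after its values were seen. This probe read 2.71 ± 0.27 in wildtype, 5.58 ± 1.1 in heterozygous and 9.72 ± 0.97 in null control pools, while another Dennd5b probe was at -0.02 ± 0.13 between heterozygous and wildtype pools (adjusted p = 0.99). With only these arrays fitted 0 probes passed. In the heat bath the first probe was at 1.29 ± 0.12 for heterozygous (adjusted p = 1.8e-05) and 1.78 ± 0.13 for null against wildtype pools (adjusted p = 9.4e-08), and the other at -0.08 and 0.18 (adjusted p = 0.87 and 0.43). Ccng1 (-0.56 ± 0.19, adjusted p = 0.79) and Cdkn1a (-0.94 ± 0.49, adjusted p = 0.80) did not pass. The camera test called the yolk sac (median -0.439, adjusted p = 2.4e-08), histone (adjusted p = 0.0051), primitive red cell (adjusted p = 0.0093) and G1/S lists (0.129, adjusted p = 0.039) with 0 genes past the threshold, and each had an adjusted p of 0.76 with an estimated correlation.

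Null and heterozygous control pools differed at 7 probes, 2 higher and 5 lower (28.6% higher, and 42.9% with median centring), with 4084 at an unadjusted p under 0.05. Higher were the probe of Dennd5b (0.82 ± 0.12) and Nlrx1 (0.70 ± 0.12), and lower were Mettl7a2 (-1.11 ± 0.18), Nosip (-0.66 ± 0.12), Acaa2 (-0.55 ± 0.10) and 2 unnamed probes. Ccng1 (-0.91 ± 0.19, adjusted p = 0.14) and Rap2b (-0.52 ± 0.13, adjusted p = 0.16) did not pass. The count changed with each pool left out. It was 1, 2, 807 and 16 without heterozygous control A, B, C and D and 4, 0, 4 and 1 without null control A to D, and it was 0 with only these arrays fitted.

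Null and wildtype embryos were compared next in the heat bath, which asks how p53 shapes transcript levels after heat. Ccng1 was lower in null pools by -2.72 ± 0.21 (adjusted p = 9.4e-08), at 1.9 ± 1 (n = 3) against 11.7 ± 1.98 (n = 4). Of 45 p53 targets 11 were lower and 0 higher (16 and 0 adjusted over the list alone), with a median of -0.262 (over all settings -0.446, without wildtype heat B and null heat B, to -0.147, in values as deposited). The camera adjusted p was 2.9e-16, and the adjusted p was 0.0027 with an estimated correlation. The list's score was 0.15 in wildtype heat B and 0.35 to 0.64 in the other wildtype pools, and -0.04 in null heat B, where Hspa1a was high, against -0.10 and -0.17 in null heat A and C. Cdkn1a was lower by -2.98 ± 0.53, Phlda3 by -1.73 ± 0.20, the thiamine transporter gene Slc19a2 by -1.53 ± 0.28, Pmaip1 by -1.48 ± 0.28, Dcxr by -1.24 ± 0.13, Sesn2 by -1.19 ± 0.20, Bbc3 by -1.01 ± 0.20 and Zmat3 by -0.64 ± 0.08. Outside the list 1700007K13Rik was lower by -2.04 ± 0.22, Ddit4l by -1.90 ± 0.24 and Mapkapk3 by -1.01 ± 0.18. Higher in null pools were Postn, a matrix protein (1.48 ± 0.31), Tecta (1.28 ± 0.16), Cyp2s1 (1.03 ± 0.22), the phosphatase gene Dusp28 (0.99 ± 0.16), the endoplasmic reticulum chaperone gene Dnajb9 (0.95 ± 0.20) and Tal2 (0.72 ± 0.15). Hspb1 (-0.27 ± 0.11, adjusted p = 0.18) and Hspa1a (-1.98 ± 1.27, adjusted p = 0.37) did not pass. Yolk sac genes had a median of 0.532 with 0 of 28 past the threshold (camera adjusted p = 5.4e-05, and adjusted p = 1 with an estimated correlation), and Trf, the transferrin gene of that list, was at 0.97 ± 0.24 (adjusted p = 0.072).

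Here 128 probes passed, 59 higher and 69 lower (46.1% higher, and 88.7% of 1617 in values as deposited, whose median over all probes was 0.143 against -0.01). With only these 7 arrays fitted 1 probe passed and all 18 named calls were lost, Ccng1 at adjusted p = 0.065, and 2 other splits of the 7 arrays gave at least as many calls (at most 1421). With the array's highest value or the split score as a covariate the count was 882 or 1076. Without wildtype heat A, B, C or D the count was 72, 262, 35 or 65 (2, 1, 7 and 4 named calls lost), and without null heat A, B or C it was 1236, 30 or 23 (0, 6 and 8 lost, among them Cdkn1a without heat C, adjusted p = 0.14). Ccng1, Phlda3, Dcxr, Zmat3, 1700007K13Rik, Ddit4l and Tecta kept their calls with each pool left out.

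**Figure D4:**
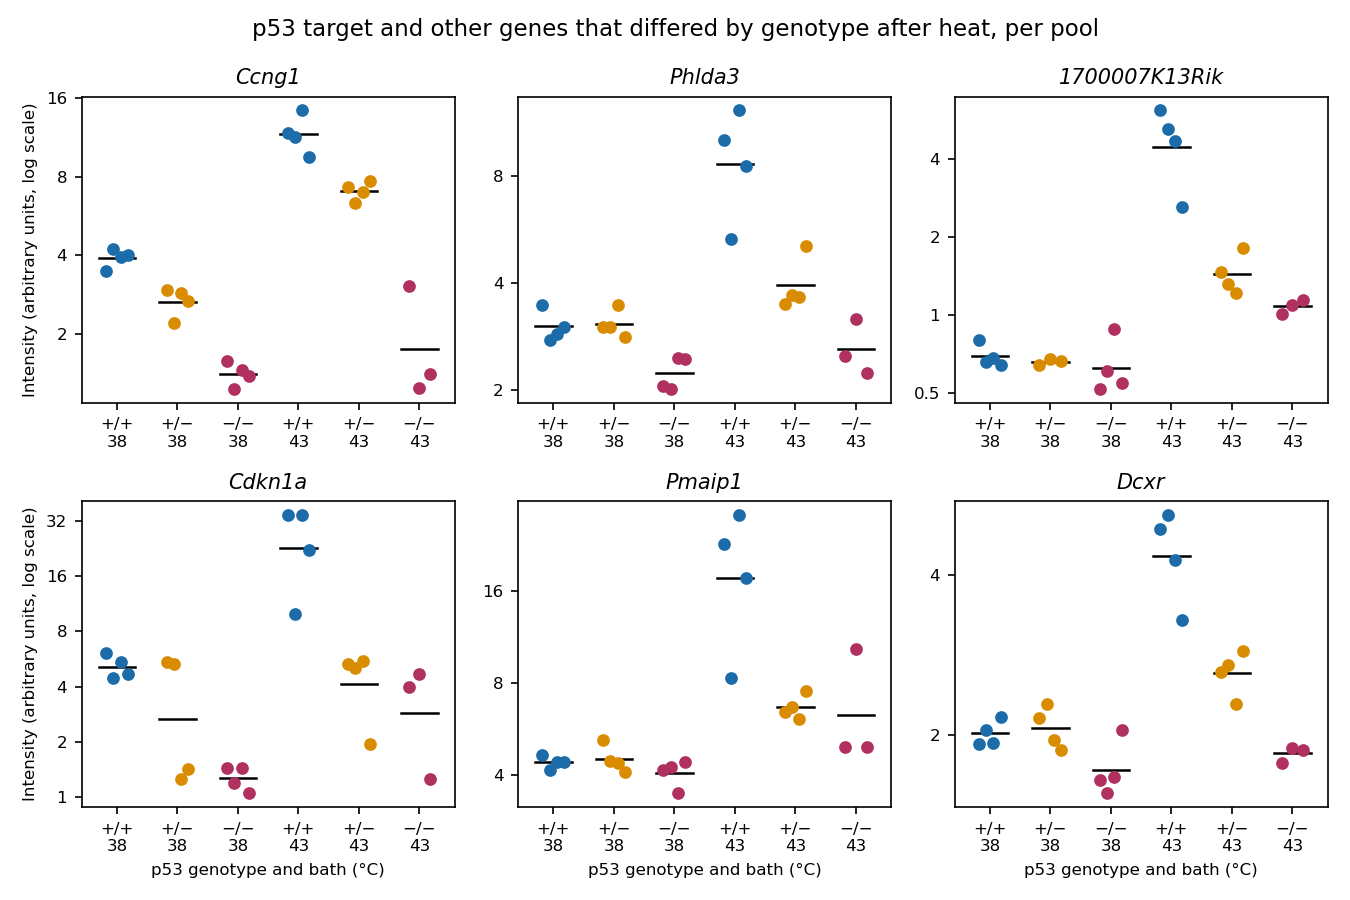
Intensity (arbitrary units, log scale) of 6 genes by p53 genotype and bath temperature in °C. Each point is a pool and each black line a group's geometric mean; Ccng1 lies at 9.5 to 14.3 in wildtype, 6.32 to 7.71 in heterozygous and 1.25 to 3.06 in null heat pools, and Phlda3 at 5.32 to 12.2, 3.5 to 5.08 and 2.24 to 3.17.

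Heterozygous pools were compared with the same 4 wildtype heat pools, so this comparison and the last share chance values of those arrays. Of 45 p53 targets 6 were lower and 0 higher (15 and 0 adjusted over the list alone), with a median of -0.22 (-0.099 in values as deposited), a camera adjusted p of 2.5e-16 and an adjusted p of 0.0026 with an estimated correlation. Hspa1a was high in wildtype heat A, C and D (list scores 0.45, 0.64 and 0.35) and low in wildtype heat B (0.15) and all 4 heterozygous pools (0.02 to 0.06), so the list's difference runs along that of Hspa1a. Cdkn1a was lower by -2.46 ± 0.49 (adjusted p = 0.049), Pmaip1 by -1.40 ± 0.26, Phlda3 by -1.14 ± 0.18, Dcxr by -0.73 ± 0.12 and Zmat3 by -0.43 ± 0.07. Lower as well were 1700007K13Rik (-1.63 ± 0.20, adjusted p = 0.00099), Ddit4l (-1.41 ± 0.22) and the growth regulator gene Pa2g4 (-0.74 ± 0.13), and higher were Tecta (1.06 ± 0.15), Cavin2 (0.68 ± 0.14) and the kinesin gene Kif1a (0.56 ± 0.10). Ccng1 (-0.71 ± 0.19, adjusted p = 0.15), Sesn2 (-0.93 ± 0.19, adjusted p = 0.052), Bbc3 (-0.79 ± 0.18, adjusted p = 0.098) and Hspa1a (-4.12 ± 1.18, adjusted p = 0.17) did not pass. Yolk sac genes had a median of 0.764, with Trf at 0.99 ± 0.22 (adjusted p = 0.098) and Spp2 at 1.10 ± 0.29 (adjusted p = 0.15). On that list 0 of 28 passed over all probes and 19 adjusted over the list alone (camera adjusted p = 6.2e-16, and adjusted p = 0.46 with an estimated correlation). In all 26 probes passed, 8 higher and 18 lower (30.8% higher, 44.4% of 9 in values as deposited with a median over all probes of 0.125 against 0.01, and 18.2% of 22 with median centring). With only these 8 arrays fitted 2 passed and all 11 named calls were lost, another split of the 8 gave 1290, and with the array's highest value or the split score as a covariate 56 or 207 passed. Without wildtype heat A to D the count was 41, 82, 5 and 8, and without heterozygous heat A to D 72, 9, 5 and 12; of the 11 named calls 2, 1, 8 and 5 and 0, 4, 7 and 4 were lost.

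Null and heterozygous heat pools differed at 1 probe, of Ccng1, at -2.01 ± 0.21 (adjusted p = 4.8e-05; 1.9 ± 1 with n = 3 against 7.07 ± 0.586 with n = 4). In all 1020 of 21979 probes had an unadjusted p under 0.05, fewer than the share of 0.05 that no difference would give. With only these arrays fitted 0 passed, and 4 other splits of them gave at least as many calls (at most 1511). Neurog2 (0.76 ± 0.21) and Wnt3a (-0.41 ± 0.11) had adjusted p-values of 0.74. Of 45 p53 targets 0 were higher and 1 lower (0 and 2 adjusted over the list alone), with a camera adjusted p of 0.00097 and an adjusted p of 0.62 with an estimated correlation.

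The differences between heat responses ask whether heat acts differently by genotype. Between null and wildtype embryos 227 probes passed, 65 with a higher and 162 with a lower response in null pools (28.6% higher, and 75.4% of 650 in values as deposited, whose median over all probes was 0.09 against -0.04). Of 45 p53 targets 6 had a lower response and 0 a higher (12 and 3 adjusted over the list alone; camera adjusted p = 0.00034, and adjusted p = 0.62 with an estimated correlation). Phlda3 was at -1.29 ± 0.27, Ccng1 at -1.25 ± 0.28, Bbc3 at -1.12 ± 0.27, Ak1, an adenylate kinase, at -1.04 ± 0.19 and Dcxr at -1.01 ± 0.18, and Pmaip1 (-1.37 ± 0.38, adjusted p = 0.079) did not pass. Other lower responses were those of 1700007K13Rik (-1.90 ± 0.30), Ttc9c (-1.82 ± 0.38) and Ddit4l (-1.56 ± 0.34), and higher ones those of Resf1 (2.0 ± 0.43), Dusp28 (1.93 ± 0.21), Tspan31 (1.79 ± 0.38), Vamp3 (1.75 ± 0.35), Pcyt2 (1.5 ± 0.28) and Epor (1.28 ± 0.29). Of these, Ttc9c was higher and Epor lower in null than in wildtype control pools. Their responses therefore hold that control difference as well. The response of Dusp28 (1.93) exceeds its difference between null and wildtype heat pools, so part of it is an opposite difference between control pools. With the split score as a covariate the count was 77 and 6 of the 14 named calls were lost. Without null heat B it was 8 and 12 were lost; without wildtype control B, C or D or heat C or D it was 41, 35, 30, 119 or 41, and without null control B it was 105. With only the 4 groups fitted it was 403 and 3 named calls were lost, Ccng1 among them (adjusted p = 0.051), and Ccng1 also missed the threshold without any 1 of wildtype control A to D, wildtype heat C or D and null heat B or C (adjusted p 0.058 to 0.13).

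Between the heterozygous and wildtype heat responses limma called 0 probes, and it called 17 without wildtype heat B. Of 21979 probes 1343 had an unadjusted p under 0.05, where no difference would give a share of 0.05. The p53 targets had a median of -0.263 with 0 past the threshold over all probes and 10 lower adjusted over the list alone (camera adjusted p = 2e-09, and adjusted p = 0.04 with an estimated correlation). Pmaip1 was at -1.44 ± 0.36, Phlda3 at -1.16 ± 0.26 and Dcxr at -0.77 ± 0.17, each with an adjusted p of 0.32. The yolk sac list had a median of 1.08 (camera adjusted p = 1.2e-25, and adjusted p = 0.12 with an estimated correlation), with Apoa2 at 2.04 ± 0.50 and Spp2 at 1.67 ± 0.41 (adjusted p = 0.32 for each). Between the null and heterozygous responses 5 probes passed (3261 at an unadjusted p under 0.05): Dusp28 (1.36 ± 0.21), Bloc1s3 (1.15 ± 0.16), Med18 (1.14 ± 0.19), Tasor (1.06 ± 0.18) and Gm26843 (-0.80 ± 0.13). Ccng1 was at -1.10 ± 0.28 (adjusted p = 0.28). With only the 4 groups fitted, or without null heat B or C, 0 of the 5 passed.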

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

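The arrays were also examined for results that stand apart, and the tests of the Hspa1a levels, of the split score and of the labels of heterozygous controls C and D, of the columns' processing and of other splits were chosen only after the result was seen.

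Hspa1a was at 78.8 to 122 on 4 heat arrays (wildtype A, C and D and null B) and at 0.881 to 2.13 on the 7 others, against 0.488 to 1.01 on control arrays. In 7 of these 7 low pools Hspb1 lies above every control array with a value (63.6 or more against at most 20, with none for wildtype control B), as does Tcte3 (8.57 or more against at most 1.62), but all heat arrays were also exported differently from the controls, so whether these pools were not heated cannot be told from it. Hspb1 was lower in these 7 pools (63.6 to 77.6) than in the 4 with high Hspa1a (81.1 to 95.6). Tcte3 overlapped between the 2 kinds of pool (8.57 to 11.7 against 9.04 to 12). Hspa1b follows Hspa1a over the heat arrays at r = 0.994, which excludes a fault of 1 probe, though the transcripts are nearly identical and their probes may cross-hybridise. In 2 of 3 genotypes pools of both kinds occur, through 1 pool each (wildtype B, with Ccng1 at 11.3, and null B, with Ccng1 at 1.25), so genotype is excluded as the whole cause and not as a part of it; this test replaced a permutation over genotype (exact p = 0.22) after its result was seen. A difference in the time from bath to collection was not tested.

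The differences between null and wildtype control pools run along the split of heterozygous control pools C and D from A and B, at r = 0.753 across tested probes, and 1742 of the 1880 called probes (92.7%) have the same sign in both. With the split score as a covariate 12 of 1880 calls are left, but the score separates null from wildtype controls completely and would take out a genotype effect as well, so genotype and another difference between arrays cannot be told apart; the median size of the called changes went from 0.59 to 0.32 at a median SE of 0.15 and 0.14. In heterozygous control C and D, 2 of 2 arrays have Ccng1 above every null control array, which argues against null pools under a wrong label. That rests on 1 gene and does not exclude it. Of 290 genes with a called probe and another probe, 56.2% moved the same way, as an effect on single probes would give, beside 74.8% of 103, 63.2% of 87 and 64.5% of 197 for heat in wildtype, heterozygous and null pools, 57.6% of 33 for null against wildtype heat pools and 75% of 32 for the difference of their responses. The correlation with the split was 0.053 for null against wildtype heat pools.

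Control and heat columns were filtered differently. Of probes with a missing value 2.31% were called with heat in wildtype pools, against 3.05% of those without, so calls were not more frequent among probes with a missing value. This cannot exclude an effect of the empty cells through quantile normalization, which acts on all probes of an array. Probes with a missing value also have fewer values to test. Of 11 heat arrays 0 were deposited with empty cells as the controls were, so processing at different times and heat cannot be told apart here.

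Other splits of the same arrays were counted as well. For heat in wildtype pools, heat in null pools and null against wildtype controls, 1 of 35 splits, the real one, gave as many calls. The highest other counts were 1, 33 and 1. For heat in heterozygous pools it was 2 of 35 (highest other 1126), for heterozygous against wildtype controls 2 of 35 (929), for null against heterozygous controls 2 of 35 (16), for null against wildtype heat pools 3 of 35 (1421), for heterozygous against wildtype heat pools 2 of 35 (1290) and for null against heterozygous heat pools 5 of 35 (1511). For the differences of responses it was 1 of 100 drawn splits for null against wildtype (highest other 6), 100 of 100 for heterozygous against wildtype, where the real count is 0 (1262), and 5 of 100 for null against heterozygous (759). The smallest possible share is 1 of 35 splits, or 1 of 100 drawn ones. The shares were not adjusted over the comparisons, and a split that mixes the groups holds their difference in its spread. These counts therefore do not exclude chance for any comparison. For null against wildtype controls they also cannot tell genotype from the split within the heterozygous controls. Splits with several times the real count point to a structure of the pools other than their group.

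Dixon's test was not run on null heat, which has 3 pools, nor on a group with a missing value. Single pools far from the other 3 of their group by Dixon's test were 27 of 555 gene and group pairs, against 27.8 for 1 in 20. In heterozygous heat D these were Aurka (20.8), Bub3 (93.7), Cdkn1a (1.95), Klf1 (0.832), Mcm7 (5.93), Phlda3 (5.08) and Prkaca (0.922). In wildtype heat they were Hspa1a and Hspa1b in pool B (0.881 and 4.22), Hspb3 in A (0.779), Cd34 and Plxna1 in C (5.01 and 0.395) and Aldh1a2 in D (13.9). In wildtype controls they were Cirbp in A (22.6), Adpgk in B (4.08), Aldh1a2 and Csk in C (6.88 and 4.66) and H3c4 in D (1.99). In null controls they were Cavin2 and Ezh1 in A (0.783 and 6.77) and Apoa2, Mt1, Spp2 and Ttc9c in B (2.84, 20.2, 3.51 and 35.8). In other heterozygous pools they were Hspa1a in control C (0.488), Gpc6 in heat A (1.08) and Pcyt2 in heat C (2.3).

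Heat responses that differ between genotypes were 227 probes for null against wildtype and 5 for null against heterozygous embryos. Among the former were Resf1 (2.0), Dusp28 (1.93), Tspan31 (1.79), Vamp3 (1.75), Pcyt2 (1.5), Epor (1.28), 1700007K13Rik (-1.90), Ttc9c (-1.82), Ddit4l (-1.56), Phlda3 (-1.29), Ccng1 (-1.25), Bbc3 (-1.12), Ak1 (-1.04) and Dcxr (-1.01), of which Ttc9c and Epor differed the opposite way between null and wildtype control pools. The latter were Dusp28 (1.36), Bloc1s3 (1.15), Med18 (1.14), Tasor (1.06) and Gm26843 (-0.80). For null against wildtype embryos the response of Dusp28 also holds an opposite control difference, as it exceeds the difference between the heat pools.

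Among probes not tested, 31 were above 3 on 1 heat array and under 1 on every other array, 19 of them on heterozygous heat C.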

How the results depend on the processing

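Of the 171 named gene values past the threshold 48 held under every setting, and 0 changed sign; 1 list value did, yolk sac genes in null against heterozygous heat pools without null heat C (0.048, adjusted p = 0.72, the range without 1 pool being -0.306 to 0.048). Of the 40 list calls 35 were lost with an estimated correlation, 12 without the 4 arrays of lowest highest value, 7 with the dim filter at the 60th percentile, 5 with probes that have a value on all arrays, 5 without wildtype heat B and null heat B and at most 4 in each other setting. With 1 pool left out 58 of 355 list calls and 340 of 1418 named gene calls were lost, and under the other settings 274 of 3013 gene calls. The cause of the changes below was not tested, beyond fewer arrays where arrays were left out or only the compared groups fitted. Centring on medians gave 290 probes for null against wildtype heat pools and 360 for the difference of their responses. A floor at the 20th percentile gave 14 for null against heterozygous controls and 41 for heterozygous against wildtype heat pools. Fitting only the groups compared gave 56 and 533 for heat in heterozygous and null pools, 4651, 0 and 0 for null against wildtype, heterozygous against wildtype and null against heterozygous controls, 1, 2 and 0 for the same pairs with heat, and 403 and 0 for the responses of null against wildtype and null against heterozygous embryos. Array weights gave 1314 for heat in wildtype pools, 6061 for null against wildtype controls, 28 and 41 for null and heterozygous against wildtype heat pools, and 2 for the response of null against heterozygous embryos. Of 55 pairs of pools with the same letter 27 correlate above 0.1 (median 0.081, range -0.357 to 0.679; 0.148, 0.596 and 0.617 for heterozygous control with null heat A, B and C). As not all do, the letter was not treated as pairing, and as a replicate block it gave 2885 for null against wildtype controls, 12 for null against heterozygous controls, and 490 and 61 for null and heterozygous against wildtype heat pools. With 1 probe per gene the counts were 0 for heterozygous against wildtype controls, 14 for these pools with heat and 8 for the response of null against heterozygous embryos.

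The next settings were added after seeing the data. Values as deposited gave 1970 and 614 for heat in wildtype and null pools, 14 for null against heterozygous controls, 1617 and 9 for null and heterozygous against wildtype heat pools and 650 for the response of null against wildtype embryos. The array's highest value as a covariate gave 1244, 1156 and 4809 for heat in wildtype, heterozygous and null pools, 1079 for null against wildtype controls, 882 and 56 for null and heterozygous against wildtype heat pools, and agreements of 0.376 (wildtype and null) and 0.729 (heterozygous and null). The split score as a covariate gave 1568, 1262 and 282 for heat, 12 and 0 for null against wildtype and heterozygous controls, 1076, 207 and 2 for null against wildtype, heterozygous against wildtype and null against heterozygous heat pools, and 77 and 0 for the responses of null against wildtype and heterozygous embryos. Without the 4 arrays of lowest highest value it was 651 for heat in null pools, 35 and 0 for heterozygous against wildtype and null against heterozygous controls, 33 for null against wildtype heat pools, 48, 7 and 0 for the 3 differences of responses, and 0.696 for the agreement of heterozygous and null pools. Without wildtype heat B and null heat B it was 263 for heat in null pools, 47 and 76 for null and heterozygous against wildtype heat pools, and 71, 20 and 0 for the differences of responses.

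With each pool left out in turn the counts ran from 362 to 812, 198 to 592 and 260 to 1489 for heat in wildtype, heterozygous and null pools. For controls they ran from 348 to 2078 (null against wildtype), 1 to 1 (heterozygous against wildtype) and 0 to 807 (null against heterozygous), and for heat pools from 23 to 1236, 5 to 82 and 1 to 5. For the differences of responses they ran from 8 to 333 (null against wildtype), 0 to 17 (heterozygous against wildtype) and 0 to 16 (null against heterozygous). Agreements ran from 0.24 to 0.476 (wildtype and heterozygous), -0.095 to 0.132 (wildtype and null) and 0.095 to 0.568 (heterozygous and null). The median of the p53 targets ran from 0.158 to 0.327 for heat in wildtype pools, -0.348 to -0.23 for null and -0.296 to -0.162 for heterozygous against wildtype heat pools.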

Other observations

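The tests of this part were fixed before the data were examined, and only the yolk sac scores per group were chosen after the list's result was seen. Of the genes given wherever measured, Mdm2, which restrains p53, passed in 0 of 12 comparisons (log2 fold changes -0.37 to 0.73, lowest adjusted p = 0.31), while Ccng1 passed in 6, Cdkn1a in 4 and Bbc3 and Pmaip1 in 3 each. The heat shock genes Hsph1 (-0.17 to 0.56, lowest adjusted p = 0.25) and Dnajb1 (-0.39 to 0.21, lowest adjusted p = 0.29) passed in 0, Hspa1b and Hspa1a in 1 each and Hspb1 in 3. Eif2s3y, on the Y chromosome, passed in 0 (-1.44 to 0.85, lowest adjusted p = 0.48), while Usp9y, also on the Y chromosome, passed in 2 (-0.50 for null against wildtype controls, adjusted p = 0.014, and 0.54 for heat in null pools, adjusted p = 0.011). Both comparisons use the same null control arrays, so the 2 Usp9y calls are not independent.

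The yolk sac list was called in 10 of 12 comparisons at the preset correlation and in 0 with an estimated one. Its mean score was -0.36 ± 0.52 in wildtype, 0.40 ± 0.27 in heterozygous (n = 4 each) and 0.23 ± 0.37 in null heat pools (n = 3). Wildtype heat A was at 0.41, within the heterozygous range of 0.14 to 0.77, and B, C and D at -0.61, -0.73 and -0.49. Endoplasmic reticulum stress (26 genes) and immediate early genes (24) were called in 2 comparisons each (lowest camera adjusted p = 0.011 and 0.0012), G1/S genes (36) in 2 (0.019) and G2/M genes (34) in 4, and 0 of these calls hold with an estimated correlation. The lists called in 0 of 12 comparisons, with their lowest camera adjusted p, were apoptosis (0.085), hypoxia and glycolysis (0.085), neural tube and brain (0.088), neural crest (0.056), somite (0.51), trophoblast and decidua (0.13), gut and epithelium (0.17), immune (0.30), sex-linked (0.062) and ribosomal protein genes (0.18) and the 255 genes near Trp53 (0.60). Some of these lists were tested only in part: 6 of 22 immune, 4 of 8 sex-linked, 13 of 33 trophoblast and decidua and 26 of 60 ribosomal protein genes. Their lack of a call covers only the tested members.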
